A study of Mus musculus with 23 samples.

How the data were processed

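RNA sequencing libraries were made from mouse germinal vesicle (GV) oocytes, zygotes and 2-cell embryos. The 23 libraries fell into 8 groups according to the labels. GV oocytes came from wild-type females at 3 weeks and at 3 months of age, from 3-week females in which Cxxc1 was deleted with Zp3-Cre, and from 3-month females in which it was deleted with Gdf9-Cre. Zygotes and 2-cell embryos came from wild-type females or from Zp3-Cre deletion females, and those of deletion females were sired by wild-type males. Each group held 3 libraries except wild-type 2-cell embryos, which held 2. The labels give no female age for the embryos and do not say whether the libraries of a group came from separate animals or separate collections, so all p-values measure only the spread between these samples, which may be technical.

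The values used were FPKM (fragment counts scaled to transcript length and to the mapped total of the library) per gene, deposited by the authors as 1 table for all samples, with a column that matched the title of each sample. Per the labels' protocols, oocytes and embryos were lysed in a column kit's buffer, RNA was purified with a small-scale column kit, and libraries were made with a NEBNext Ultra RNA kit. Per the submitters' processing notes, CASAVA 1.4, TopHat2 2.0.12, Cufflinks 2.2.1 and SAMtools were among the tools used, and the builds mm10 and mm9 were named without saying which one applied to the RNA data, so no coordinates are given. Strand, poly(A) selection, gene annotation and any spike-in are not given in the sources used here. Bisulfite sequencing named in the labels was not analysed here.

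FPKM carries no read counts, so the depth of each library is unknown and no counting error can be attached to a value. The FPKM columns summed to different totals, from 295901 in a wild-type 2-cell library to 420415 in a 3-month Gdf9-Cre library. FPKM is relative to the total of each library, so a group with a different amount of mRNA per cell cannot be told from one with another composition. An exact 0 can be a failed estimate, and such a gene is described as listed at 0. Reads of near-identical family members, such as Obox, Usp17l, Nlrp, histone and ribosomal protein genes or the pair Hspa1a and Hspa1b, could be split between copies by the authors' quantification, and values of single members are uncertain for that reason. Without a statement on strand, overlapping and antisense transcripts cannot be told apart. Of the 24506 entries of the table, 27 carried names changed into dates by spreadsheet software, 4 of which shared a name with another; they stayed in the tests and are not named.

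Values were analysed as log2(FPKM + 1), a log2 transform computed here from the deposited FPKM. Genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 13776 genes. A linear model with 8 group means was fitted to all 23 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step and 15 residual degrees of freedom shared by all groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The comparisons were the 4 deletion groups against their own wild-type group, the wild-type groups against one another by age and by stage, 3 tests of whether a deletion effect differed between stages or between the GV models, and the average of the 4 deletion effects. Groups, tests, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except for those said to have been added later.

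Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, against all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison and at least 5 tested members per list. Of 32 lists fixed, covering chromatin, oocyte and embryo functions and markers of other cell types, 30 could be tested, and the text describes the lists that were called or that carry named genes. The same test with the correlation estimated from the residuals was the alternative, and its adjusted p is given beside each call that it ended. List members were counted as risen or fallen over all genes tested and again with the adjustment over the list alone. Sets of genes that rose or fell between zygote and 2-cell stage were defined by a log2 change of at least 2 in the stage effect averaged over both genotypes, with weights that make it uncorrelated with the tested difference between genotypes.

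Named genes followed a fixed rule. For each deletion comparison these were Cxxc1, the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean FPKM of at least 5 over both groups and no overlap between the groups' libraries, and up to 3 called members per list with the largest change, or 2 members with the highest FPKM where none was called. For the other comparisons the rule took 5 genes in each direction, with list members chosen in the same way. Predicted gene models may be left out. Alternatives to the main choices were a pseudocount of 0.1, no filter, an FPKM of at least 5 in at least 2 libraries, median-of-ratios scaling, quantile normalization, a fit on only the groups compared, the replicate number as a block, array weights, and leaving out each library in turn. Single values are means ± SD over the libraries of a group.

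The fit was tested on simulated data in which 200 genes were changed by known amounts. Of genes changed by 2-fold, 83.0%, 85.0%, 86.0% and 79.0% were recovered in the designs of 3-week oocytes, 3-month oocytes, zygotes and 2-cell embryos. These held 13116, 13111, 13119 and 13115 genes. False calls numbered 6, 13, 8 and 17 in the same order, or 3.21%, 6.63%, 4.17% and 8.81% of the calls. That share exceeded 0.05 in the 3-month and 2-cell designs.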

Results

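The data comprised 23 RNA sequencing libraries of mouse oocytes and early embryos with and without Cxxc1. This gene encodes CFP1, the CXXC zinc-finger subunit of the SETD1 complexes that methylate histone H3 lysine 4. Fully grown germinal vesicle (GV) oocytes rest in the first meiotic prophase. Embryos live on stored maternal RNA until their own genome is switched on, in the mouse mainly at the 2-cell stage. Zp3-Cre deletes floxed genes in growing oocytes, and Gdf9-Cre does so from an earlier follicle stage. There were 3 libraries in each of 7 groups and 2 libraries of wild-type 2-cell embryos. The depth of each library is unknown because only FPKM was used. Genes at an FPKM of at least 1 numbered 10547 to 10719 in wild-type GV libraries, 11101 to 11226 in 3-week Zp3-Cre oocytes and 11541 to 11783 in 3-month Gdf9-Cre oocytes. They numbered 8663 to 8875 in wild-type zygotes, 9748 to 9932 in deletion zygotes, 11262 and 11284 in wild-type 2-cell embryos, and 10187 to 12333 in deletion 2-cell embryos.

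Deletion 2-cell library 3 stood apart from its group. Its correlation across genes with the other deletion 2-cell libraries was 0.942 and 0.936, against 0.983 between those. It held 12333 genes at an FPKM of at least 1, against 10481 and 10187, and carried transcripts that mark other cell types. FPKM totals were 335591 to 347101 in wild-type and 350773 to 357999 in deletion zygotes. In 3-month oocytes they were 377444 to 380906 in wild type and 415063 to 420415 after deletion. Calls were also counted under median-of-ratios scaling and quantile normalization, which centre the libraries and so cannot settle the balance of higher and lower genes.

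Cxxc1, the targeted gene, was lower in each deletion group. In 3-week oocytes Cxxc1 was at 39.9, 37.9 and 41.5 FPKM in wild type and at 0.893, 1.02 and 1.49 after Zp3-Cre deletion. The log2 fold change was -4.27 ± 0.260 (SE, adjusted p = 8.88e-10). In 3-month oocytes Cxxc1 was at 35.7, 36.0 and 38.5 FPKM in wild type and at 0.975, 0.698 and 1.10 after Gdf9-Cre deletion, a log2 fold change of -4.30 ± 0.260 (SE, adjusted p = 4.40e-10). Zygotes held 29.1, 24.0 and 30.7 FPKM of Cxxc1 in wild type and 1.29, 1.11 and 1.61 after maternal deletion, a log2 fold change of -3.63 ± 0.260 (SE, adjusted p = 6.19e-10). In 2-cell embryos Cxxc1 was at 9.94 and 11 FPKM in wild type and at 1.17, 0.626 and 4.16 after deletion, a log2 fold change of -2.13 ± 0.291 (SE, adjusted p = 2.37e-06). Without deletion library 3 the log2 fold change was -2.61. Embryos of deletion females carry a wild-type paternal allele, and a whole-gene FPKM can keep reads from exons that were not deleted.

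**Figure D1:**
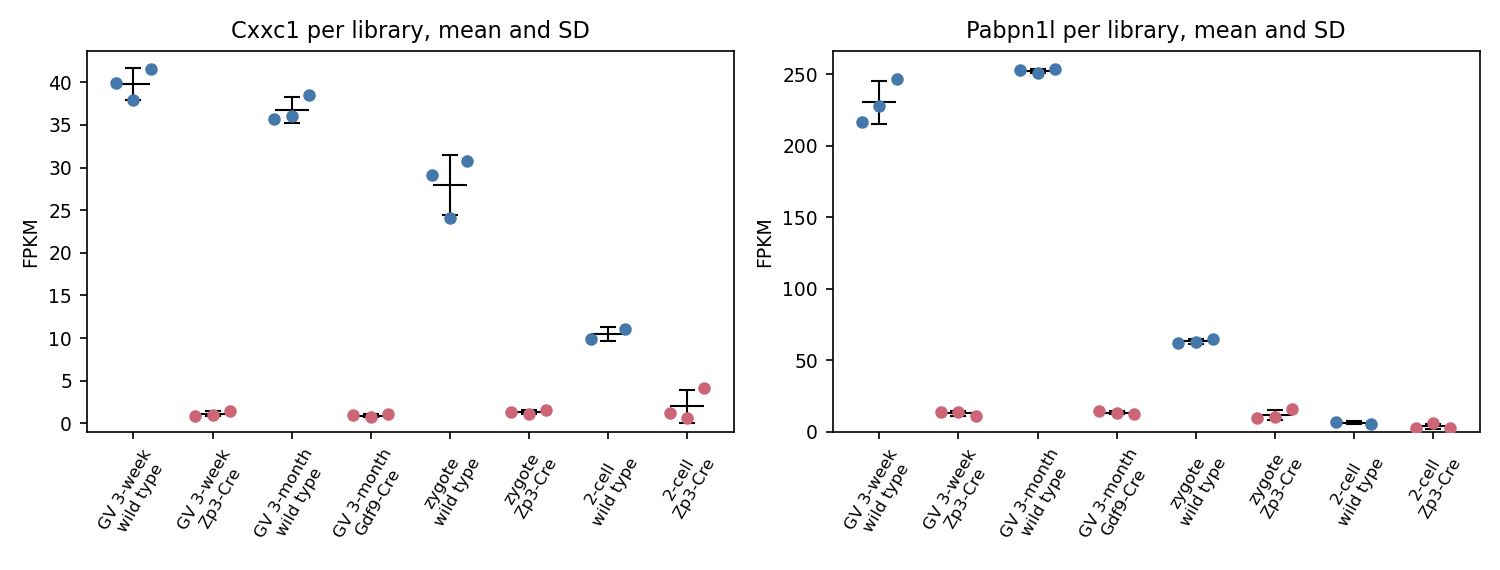
FPKM of Cxxc1 and of Pabpn1l in each of the 23 libraries, by group, with points for libraries and bars for the mean and SD. Cxxc1 lay between 35.7 and 41.5 FPKM in wild-type GV libraries and at most at 1.49 in the GV deletion libraries, and Pabpn1l fell from 230.5 ± 15 to 13 ± 1.91 FPKM in 3-week oocytes.

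Loss of Cxxc1 in oocytes of 3-week females lowered a group of oocyte transcripts and raised others. Pabpn1l, an oocyte poly(A)-binding protein gene, fell from 230.5 ± 15 to 13 ± 1.91 FPKM (SD, n = 3 in each group). Its log2 fold change was -4.06 ± 0.189 (SE, adjusted p = 6.51e-11). Pnpla3, which encodes a lipid-droplet acyl hydrolase, fell from 66.0 ± 1.51 to 0.304 ± 0.0246 FPKM (log2 fold change -5.68, adjusted p = 5.79e-10). Wild-type 3-month oocytes held at most 0.181 FPKM of Pnpla3, so its fall cannot be assigned to deletion alone. The zinc-finger gene Insm1 fell from 28.2 ± 0.428 to 2.78 ± 0.882 FPKM, Extl1 from 19.7 ± 0.512 to 2.44 ± 1.30 and the splicing regulator Rbm4 from 13.5 ± 0.568 to 1.78 ± 1.08. In the other direction, the deubiquitinase gene Stambpl1 rose from 0.724 ± 0.173 to 40.5 ± 10.6 FPKM (log2 fold change 4.56, adjusted p = 6.82e-10). The metallothionein Mt1 rose from 5.35 ± 0.391 to 78.3 ± 4.96 FPKM and the small heat-shock protein gene Hspb1 from 12.3 ± 3.55 to 151 ± 31.5. The inducible chaperone gene Hspa1a rose from 5.84 ± 1.14 to 52.7 ± 13.3 FPKM and the monocarboxylate transporter Slc16a6 from 1.11 ± 0.328 to 25.3 ± 4.21. The autophagy gene Gabarapl1 rose from 0.584 ± 0.108 to 13.1 ± 1.64 FPKM and Plac1 from 0.429 ± 0.299 to 11.5 ± 1.23. Stress and immediate early genes as a list had 6 risen and 3 fallen members of 25 (7 and 3 over the list alone), with a median log2 fold change of 0.31, and were not called (camera adjusted p = 0.407). Snora47 was listed at 0 in wild type and at 116 ± 48.6 FPKM after deletion.

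Genes for secreted factors and the zona pellucida were called lower as a list in 3-week oocytes. List medians here and below are medians of log2 fold changes. Secreted factors and zona genes had 0 risen and 9 fallen members of 16 (0 and 10 over the list alone), with a median log2 fold change of -0.53. Camera gave adjusted p = 3.75e-05, and 0.301 with an estimated correlation. Astl, the protease that cleaves the zona pellucida after fertilization, fell from 285 ± 3.74 to 149 ± 12.8 FPKM, Oosp3 from 211 ± 32.9 to 123 ± 23.4 and Fgf8 from 22.3 ± 2.26 to 12.2 ± 2.76. Oocyte transcription factors had 2 risen and 5 fallen members of 17 (2 and 5 over the list alone), with a median of -0.0394. Camera gave adjusted p = 0.0466, and 0.417 with an estimated correlation. The homeobox gene Obox1 fell from 501 ± 11.7 to 146 ± 19.7 FPKM, Obox2 from 687 ± 46.6 to 237 ± 36.7 and Obox5 from 438 ± 3.98 to 139 ± 14.6. Maternal effect genes, whose products the early embryo needs, had 3 risen and 11 fallen members of 30 (3 and 11 over the list alone). The test pointed down (camera adjusted p = 0.0411, and 0.477 with an estimated correlation), as did the mean of -0.13. The median was 0.0181 as deposited but -0.0928 under median-of-ratios scaling and -0.00922 under quantile normalization. Nlrp9b fell from 210.0 ± 4.29 to 58.7 ± 1.89 FPKM and Nlrp4e from 74.6 ± 6.54 to 24.3 ± 1.81. Basp1 rose from 3.85 ± 1.23 to 34.6 ± 7.07 FPKM.

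Lists of mitochondrial respiration and proteasome genes were called higher in 3-week deletion oocytes, though most of their members did not pass. Oxidative phosphorylation genes had 23 risen and 1 fallen members of 82 (23 and 1 over the list alone), with a median of 0.35. Camera gave adjusted p = 0.0114, and 0.497 with an estimated correlation. Proteasome genes had 15 risen and 1 fallen members of 44 (15 and 1 over the list alone), with a median of 0.36. Camera gave adjusted p = 0.0114, and 0.477 with an estimated correlation. Psmd3 rose from 93.5 ± 4.21 to 143 ± 7.79 FPKM, and Psmg1 moved against the list from 37.5 ± 0.892 to 21.5 ± 1.03. Under median-of-ratios scaling 15 respiratory genes rose and 2 fell (median 0.24), and 7 proteasome genes rose and 2 fell (0.25). Outside the called lists, the methyltransferase core subunit Ash2l rose from 21.8 ± 1.06 to 47.7 ± 5.09 FPKM. The maintenance DNA methyltransferase Dnmt1 fell from 1246 ± 18.8 to 590.2 ± 75.6 FPKM and the methylcytosine dioxygenase Tet3 from 58.4 ± 5.99 to 31.1 ± 1.17. The oocyte cap-binding protein Eif4e1b fell from 889.7 ± 7.92 to 418 ± 9.52 FPKM, the deadenylase adaptor Btg4 from 392 ± 10.2 to 282 ± 18.5 and the meiotic kinase gene Mos from 228 ± 10.7 to 125 ± 0.490, a call that Mos lost in 6 of 14 alternatives (adjusted p up to 0.0664). The F-box gene Fbxw15 fell from 423 ± 10.3 to 179 ± 23.4 FPKM, the repair factor Trp53bp1 from 19.9 ± 0.649 to 8.38 ± 0.285 and the small-RNA methyltransferase Henmt1 from 65.6 ± 2.34 to 20.3 ± 2.74.

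In 3-week oocytes 4081 of 13776 genes were called, 2524 higher and 1557 lower. Of these, 683 changed at least 2-fold, 413 higher and 270 lower. The higher share of the calls was 61.8% as deposited, 45.4% under median-of-ratios scaling and 48.2% under quantile normalization.

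In oocytes of 3-month females, where Gdf9-Cre removed Cxxc1, Pabpn1l and Insm1 fell and Stambpl1, Hspb1, Slc16a6 and Plac1 rose, as in the younger oocytes. Pabpn1l fell from 253 ± 1.36 to 13.5 ± 0.963 FPKM (SD, n = 3 in each group). Its log2 fold change was -4.13 ± 0.189 (SE, adjusted p = 1.91e-11). Insm1 fell from 31.0 ± 3.39 to 2.72 ± 0.197 FPKM, the chromatin regulator Arid5b from 36.8 ± 0.833 to 5.0 ± 1.41 and Cd7 from 92.5 ± 6.58 to 14.1 ± 1.32. Stambpl1 rose from 1.03 ± 0.336 to 75.9 ± 15.8 FPKM (log2 fold change 5.23, adjusted p = 6.30e-11). Hspb1 rose from 11.9 ± 0.936 to 297 ± 43.0 FPKM, Slc16a6 from 0.599 ± 0.0704 to 29.2 ± 3.12 and Plac1 from 0.819 ± 0.235 to 32.4 ± 5.6. The transcription factor gene Sox3 rose from 0.0989 ± 0.0227 to 16.2 ± 1.88 FPKM, Hspa1a from 5.68 ± 0.816 to 83.0 ± 5.12 and the cytokine subunit Il23a from 2.31 ± 1.44 to 38.3 ± 2.68. Ash2l rose from 18.0 ± 0.409 to 53.1 ± 1.88 FPKM and the general transcription factor Gtf2b from 252 ± 5.73 to 760.4 ± 37.1.

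The secreted and zona list was also called lower in 3-month oocytes, and the respiratory, ribosomal, proteasome and activation lists were called higher, though most ribosomal protein genes did not pass and no call held with an estimated correlation. The medians of these lists kept their sign under each scaling, but sizes and calls of the lists that rose became smaller. Of 16 secreted factors and zona genes, 2 were risen and 11 fallen (2 and 11 over the list alone), and the median was -0.56. In camera the secreted and zona list had adjusted p = 1.79e-04, and 0.232 with an estimated correlation. Fgf8 fell from 33.1 ± 3.68 to 11.1 ± 1.97 FPKM, the gamete fusion gene Cd9 from 61.6 ± 6.19 to 27.1 ± 0.719 and the receptor kinase gene Kit from 106 ± 2.21 to 53.1 ± 2.24. Obox1 fell from 508 ± 28.4 to 105 ± 9.08 FPKM, Obox2 from 604 ± 48.1 to 133 ± 3.05 and Nlrp9b from 197 ± 11.3 to 50.6 ± 2.58. Of 82 oxidative phosphorylation genes, 54 were risen and 0 fallen (57 and 0 over the list alone), and the median was 0.71. In camera the respiratory list had adjusted p = 2.00e-05, and 0.232 with an estimated correlation. Cox8c rose from 0.780 ± 0.145 to 20.7 ± 5.13 FPKM and Ndufa4l2 from 1.38 ± 1.03 to 12.7 ± 1.5. Ribosomal protein genes had 35 risen and 1 fallen members of 83 (35 and 1 over the list alone), with a median of 0.62. Camera gave adjusted p = 0.0253, and 0.713 with an estimated correlation. Of 44 proteasome genes, 31 were risen and 1 fallen (33 and 1 over the list alone), and the median was 0.52. In camera the proteasome list had adjusted p = 0.00503, and 0.440 with an estimated correlation. Genome activation genes had 30 risen and 3 fallen members of 54 (30 and 3 over the list alone), with a median of 0.59. Camera gave adjusted p = 0.0253, and 0.645 with an estimated correlation. Under median-of-ratios scaling 37 respiratory, 23 ribosomal, 13 proteasome and 23 activation genes rose, with medians of 0.47, 0.37, 0.27 and 0.43. Under quantile normalization 18 activation genes rose (median 0.28). The largest rises in the activation list were the heat-shock genes Hspa1a and Hspa1b, the latter from 14.7 ± 1.36 to 142 ± 3.40 FPKM, and Usp17le, from 0.0324 ± 0.0561 to 10.4 ± 1.42.

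Markers of granulosa cells, the follicle cells around the oocyte, were higher in the same libraries. Of 19 tested markers 13 rose and 0 fell (13 and 0 over the list alone), with a median of 0.99. Camera placed this list just above the threshold (adjusted p = 0.0515), and 10 and 7 members were called higher under median-of-ratios scaling and quantile normalization. Inha was at 63.3, 33.6 and 24.0 FPKM in the Gdf9-Cre libraries against 3.34 ± 0.968 in wild type. Amh was at 32.4, 13.5 and 16.1 against 3.18 ± 0.649, and Gja1 at 18.5, 7.01 and 7.47 against 1.4 ± 0.602.

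In 3-month oocytes 6818 genes were called, 4718 higher and 2100 lower. Of these, 1861 changed at least 2-fold, 1441 higher and 420 lower. The higher share was 69.2% as deposited, 48.3% under median-of-ratios scaling and 46.6% under quantile normalization. These scalings shifted the median of all genes by -0.17 and -0.22 on the log2 scale.

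The effects of deletion overlapped between the GV models, in which Cre driver and female age changed together. They shared 2129 higher genes, against 864 for independent lists, and 1138 lower genes, against 237. The shared higher genes numbered 1182 under median-of-ratios scaling and 1332 under quantile normalization. The log2 fold changes correlated across genes with r = 0.744 (Spearman 0.742), genes not being independent replicates. A test of the difference called 673 genes, 441 with a higher and 232 with a lower effect in Gdf9-Cre oocytes. The higher share of 65.5% became 37.2% under median-of-ratios scaling and 32.5% under quantile normalization, with shifts of the median of all genes by -0.10 and -0.13. The effect on Pnpla3 differed by 5.69 ± 0.465 (log2, SE, adjusted p = 1.00e-06), since wild-type Pnpla3 was at 66.0 ± 1.51 FPKM at 3 weeks and 0.155 ± 0.0442 at 3 months. Inha (3.06), Amh (1.81), Cox8c (2.65) and the p53 target Sesn1 (1.51) had a higher effect with Gdf9-Cre. Tet3 (-0.88), Trp53bp1 (-0.67), Mt1 (-1.47), Tceal8 (-2.86) and Zfp109 (-2.68) had a lower effect. With a pseudocount of 0.1 Inha (adjusted p = 0.124), Amh (0.0754), Sesn1 (0.0684) and Mt1 (0.216) lost the call, Inha also without any 1 of 3 libraries. Granulosa markers had 2 higher and 0 lower members of 19 (4 and 0 over the list alone), with a median difference of 0.95. Camera gave adjusted p = 0.0107, and 0.794 with an estimated correlation. Across 82 oxidative phosphorylation genes the median difference was 0.35, with 4 higher and 0 lower (4 and 0 over the list alone). The respiratory list had camera adjusted p = 7.48e-04, and 0.794 with an estimated correlation. Of 83 ribosomal protein genes, 2 were higher and 0 lower (2 and 0 over the list alone), and the median difference was 0.40. In camera the ribosomal list had adjusted p = 0.0107, and 0.935 with an estimated correlation. The count of 673 was 3228 with array weights, 2448 in a fit on only these groups and 363 with a pseudocount of 0.1. It was 360 to 435 without any 1 of 9 of the 12 libraries, all but Gdf9-Cre library 3 and Zp3-Cre libraries 1 and 3.

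Zygotes of deletion females held more of many transcripts that were scarce in wild-type zygotes. The U6-associated splicing factor Lsm4 rose from 2.24 ± 1.30 to 73.7 ± 10.7 FPKM (SD, n = 3 in each group). Its log2 fold change was 4.59 ± 0.192 (SE, adjusted p = 2.34e-13). The pluripotency-associated gene Dppa5a rose from 9.55 ± 1.83 to 248 ± 36.7 FPKM and the mitochondrial import chaperone Timm9 from 3.38 ± 1.09 to 95.4 ± 21.0. Hmgb2 rose from 13.8 ± 0.825 to 319.9 ± 17.7 FPKM and Paip2 from 4.13 ± 0.456 to 94.9 ± 21.5. The kinase gene Camk2g rose from 8.74 ± 0.846 to 165 ± 7.92 FPKM and the histone gene Hist1h2bc from 3.33 ± 1.02 to 93.3 ± 3.49. Oog3 fell from 910.4 ± 67.4 to 159 ± 13.8 FPKM, Insm1 from 49.5 ± 7.79 to 6.02 ± 1.14 and Pabpn1l from 63.3 ± 1.76 to 12 ± 3.61. The integrin gene Itga9 fell from 63.8 ± 3.86 to 12 ± 2.11 FPKM and S100a14 from 40.05 ± 3.08 to 7.88 ± 2.44. Oocyte transcripts moved in either direction. Zp2 rose from 24.1 ± 1.95 to 397 ± 71.7 FPKM, Zp3 from 36.7 ± 0.992 to 206 ± 46.4 and Cd9 from 2.17 ± 0.404 to 40.3 ± 10.2. Nobox rose from 19 ± 0.198 to 125 ± 14.7 FPKM and Mos from 7.34 ± 0.782 to 65.4 ± 8.13. The subcortical maternal complex gene Khdc3 rose from 9.43 ± 0.568 to 105 ± 29.3 FPKM and Npm2 from 35.9 ± 5.45 to 162 ± 29.5. Obox1 fell from 1062 ± 104 to 324 ± 3.34 FPKM, Obox5 from 1176 ± 69.8 to 351 ± 41.1 and Tet3 from 584 ± 35.0 to 276 ± 6.77.

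Genes of cell machinery made up the lists called higher in zygotes. Oxidative phosphorylation genes had 57 risen and 4 fallen members of 82 (61 and 4 over the list alone), with a median of 1.24. Camera gave adjusted p = 1.70e-08, and 0.148 with an estimated correlation. Ndufa1 rose from 6.59 ± 0.923 to 121 ± 19.6 FPKM and Uqcr11 from 7.40 ± 3.26 to 117 ± 12. Across 44 proteasome genes the median was 0.80, with 31 risen and 1 fallen (32 and 1 over the list alone). The proteasome list had camera adjusted p = 1.79e-04, and 0.182 with an estimated correlation. Across 83 ribosomal protein genes the median was 0.75, with 40 risen and 0 fallen (40 and 0 over the list alone). The ribosomal list had camera adjusted p = 0.00250, and 0.796 with an estimated correlation. Rpsa rose from 2.02 ± 0.619 to 43.4 ± 5.35 FPKM and Rpl41 from 76.7 ± 10.2 to 1062 ± 90.6. Nucleolar genes had 30 risen and 3 fallen members of 52 (32 and 3 over the list alone), with a median of 0.52. Camera gave adjusted p = 0.00607, and 0.182 with an estimated correlation. Spliceosome genes had 35 risen and 5 fallen members of 62 (35 and 6 over the list alone), with a median of 0.56. Camera gave adjusted p = 0.0338, and 0.418 with an estimated correlation. Under median-of-ratios scaling the medians were 0.79 for respiratory, 0.35 for proteasome, 0.22 for ribosomal and 0.20 for nucleolar genes, and under quantile normalization 0.70, 0.39, 0.25 and 0.19. Risen and fallen members under the former were 49 and 11, 21 and 8, 29 and 4, and 17 and 8 in the same order. The spliceosome median was 0.0292 under median-of-ratios scaling and 0.12 under quantile normalization, and the calls were 21 risen and 22 fallen under the former. The lists called lower belonged to histone H3 lysine 4 methylation. H3K4 methyltransferase genes had 2 risen and 7 fallen members of 17 (2 and 8 over the list alone), with a median of -0.18. Camera gave adjusted p = 0.0423, and 0.537 with an estimated correlation. Ash2l rose from 11.3 ± 0.295 to 29.6 ± 0.881 FPKM against its list. H3K4 demethylase genes had 0 risen and 3 fallen members of 7 (0 and 3 over the list alone), with a median of -0.21. Camera gave adjusted p = 0.0465, and 0.182 with an estimated correlation. Rcor2 fell from 13.8 ± 2.06 to 8.01 ± 0.958 FPKM. Under median-of-ratios scaling the methyltransferase and demethylase medians were -0.78 and -0.80.

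Lists of oocyte and embryo genes were not called in zygotes. Secreted factors and zona genes (8 risen and 3 fallen of 16, 8 and 3 over the list alone; camera adjusted p = 0.153) had a median of 0.49 as deposited but -0.11 under median-of-ratios scaling and 0.35 under quantile normalization. Maternal effect genes (17 risen and 9 fallen of 30, 17 and 9 over the list alone; camera adjusted p = 0.185) had a median of 0.96 as deposited but 0.35 under median-of-ratios scaling, with 14 risen and 11 fallen, and 0.58 under quantile normalization. Genome activation genes (13 risen and 1 fallen of 54, 11 and 1 over the list alone; camera adjusted p = 0.876) had a median of 0.12 as deposited but 0.0220 under median-of-ratios scaling, with 10 risen and 6 fallen, and -0.0569 under quantile normalization, with 8 and 5. In zygotes 6431 genes were called, 4860 higher and 1571 lower. Of these, 2281 changed at least 2-fold, 2048 higher and 233 lower. The higher share was 75.6% as deposited but 41.1% under median-of-ratios scaling and 44.6% under quantile normalization, which moved the median of all genes by -0.25 and -0.29. Whether more genes rose than fell in zygotes stays open.

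In 2-cell embryos the transcripts of embryonic genome activation were low after maternal deletion, and many maternal transcripts were high. The alkaline phosphatase gene Alppl2 fell from 289 ± 23.3 to 3.76 ± 1.38 FPKM (SD, n = 2 wild-type and 3 deletion libraries). Its log2 fold change was -5.97 ± 0.184 (SE, adjusted p = 3.99e-15). The phosphate transporter Slc34a2 fell from 164 ± 7.49 to 1.76 ± 0.0546 FPKM, the homeobox gene Crxos from 126 ± 11.1 to 1.93 ± 0.677 and Sp6 from 64.7 ± 9.53 to 0.708 ± 0.165. Of 54 genome activation genes, 2 were risen and 48 fallen (2 and 48 over the list alone), and the median was -2.63. In camera the activation list had adjusted p = 1.16e-15, and 0.0270 with an estimated correlation. The activation median was -2.90 under median-of-ratios scaling and -2.79 under quantile normalization. Tdpoz1 fell from 28.0 ± 4.96 to 0.318 ± 0.259 FPKM, Ubtfl1 from 31.7 ± 2.32 to 0.496 ± 0.179 and Tmem92 from 75.1 ± 0.349 to 3.10 ± 0.524. Of 52 nucleolar genes, 7 were risen and 40 fallen (7 and 40 over the list alone), and the median was -1.33. In camera the nucleolar list had adjusted p = 8.81e-09, and 0.00285 with an estimated correlation. Rrp9 fell from 150.4 ± 17.3 to 5.61 ± 0.684 FPKM, the ribosomal RNA methyltransferase Nop2 from 71.4 ± 2.54 to 3.26 ± 1.4 and the RNA polymerase subunit Polr1c from 108 ± 12.3 to 6.81 ± 2.12.

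Single regulator genes were among the largest falls in 2-cell embryos, while most lists of regulators held members that rose and members that fell. Cell cycle genes had 20 risen and 15 fallen members of 42 (21 and 15 over the list alone; camera adjusted p = 0.623), with a median of 0.27. Histone variants and chaperones had 18 and 8 of 30 (18 and 8; 0.510), with a median of 0.49. Repressive chromatin genes had 15 and 15 of 36 (15 and 15; 0.623), and RNA polymerase II factors 28 and 33 of 76 (29 and 33; 0.778), with medians of -0.10 and -0.15. With median-of-ratios scaling these 4 lists had 19 and 18, 11 and 11, 13 and 19, and 24 and 37, with medians of 0.0156, 0.22, -0.38 and -0.41. Obox6 fell from 77.6 ± 0.542 to 2.2 ± 0.760 FPKM, Obox3 from 127 ± 6.99 to 5.35 ± 0.423 and the H3K4 demethylase Kdm5b from 69.2 ± 6.58 to 4.34 ± 2.42. The G1 cyclin gene Ccne1 fell from 157 ± 13.2 to 9.24 ± 1.66 FPKM, the NuRD subunit Mta2 from 147 ± 8.0 to 5.56 ± 2.15 and the deacetylase Hdac1 from 72.7 ± 14.2 to 11.5 ± 1.88. Transcription elongation and acetylation genes had 10 risen and 19 fallen members of 35 (10 and 19 over the list alone), with a median of -0.36. Camera gave the elongation list adjusted p = 0.0401, and 0.289 with an estimated correlation. Its median was -0.62 under median-of-ratios scaling, with 6 risen and 23 fallen. Without deletion library 3 the elongation list was no longer called (adjusted p = 0.0926). Ribosomal protein genes had 12 risen and 38 fallen members of 83 (11 and 38 over the list alone), with a median of -0.84. Camera gave adjusted p = 0.0376, and 0.882 with an estimated correlation. Without that library 61 ribosomal protein genes fell and 10 rose (camera adjusted p = 9.42e-07).

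Maternal transcripts were high in the same embryos. Maternal effect genes had 24 risen and 4 fallen members of 30 (25 and 4 over the list alone), with a median of 1.38. Camera gave adjusted p = 2.40e-05, and 0.0601 with an estimated correlation. The maternal RNA-binding protein gene Zar1 rose from 30.9 ± 0.588 to 372 ± 44.3 FPKM, Padi6 from 49.98 ± 11.4 to 542 ± 133 and the imprint-maintaining gene Zfp57 from 57.7 ± 1.82 to 748 ± 243. Across 16 secreted factors and zona genes the median was 1.5, with 14 risen and 0 fallen (14 and 0 over the list alone). The secreted and zona list had camera adjusted p = 1.89e-04, and 0.210 with an estimated correlation. Oosp2 rose from 13.4 ± 0.219 to 170.5 ± 28.4 FPKM, Zp2 from 24.7 ± 2.57 to 272 ± 61.5 and Zp3 from 33.2 ± 2.17 to 140.0 ± 61.5. The oocyte linker histone H1foo rose from 70.6 ± 15.8 to 479 ± 8.53 FPKM and Nobox from 11.1 ± 0.879 to 165 ± 33.7. Dazl rose from 10.7 ± 1.70 to 87.0 ± 23.4 FPKM and the signalling regulator Rgs2 from 6.87 ± 3.77 to 113 ± 46.6. Oocyte ubiquitin ligase genes had 14 risen and 2 fallen members of 21 (15 and 2 over the list alone), with a median of 0.76. Camera gave adjusted p = 0.00781, and 0.285 with an estimated correlation. Of 82 oxidative phosphorylation genes, 51 were risen and 10 fallen (51 and 10 over the list alone), and the median was 0.91. In camera the respiratory list had adjusted p = 2.63e-04, and 0.279 with an estimated correlation. DNA damage response genes had 21 risen and 6 fallen members of 29 (21 and 6 over the list alone), with a median of 0.86. Camera gave adjusted p = 0.0472, and 0.289 with an estimated correlation. All lists called in 2-cell embryos kept the sign of their median under each scaling.

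Library 3 of the deletion 2-cell embryos held transcripts of ovarian and blood cells that the other libraries of its group lacked or held at lower levels. Saa3 was at 459 FPKM there against 7.15 and 1.65 in the other deletion libraries. Cyp11a1 was at 82.3 FPKM, Clu at 82.0, Vim at 61.9, Col1a2 at 38.2, Col3a1 at 34.9, Dcn at 33.4, Col1a1 at 27.9 and Lyz2 at 24.8. Dcn was also at 1.78 to 7.90 FPKM in every other deletion library, against at most 0.881 in any wild-type one. The granulosa hormone gene Amh was at 0.229. Of the markers detected in 2-cell libraries, 7 of 9 for stroma and theca, 13 of 20 for granulosa and 8 of 12 for blood cells were at least 4 times as high as in either other deletion library. For oviduct and sperm these numbers were 2 of 5 and 0 of 11. The granulosa list (4 risen and 3 fallen of 19, 4 and 3 over the list alone; camera adjusted p = 0.778), the stroma and theca list (1 risen and 0 fallen of 5, 1 and 0 over the list alone; camera adjusted p = 0.778) and the blood list (2 risen and 2 fallen of 11, 2 and 1 over the list alone; camera adjusted p = 0.952) were not called in the group comparison. In 2-cell embryos 9159 genes were called, 5112 higher and 4047 lower. Of these, 5122 changed at least 2-fold, 2470 higher and 2652 lower. The higher share was 55.8% as deposited, 46.0% under median-of-ratios scaling and 56.1% under quantile normalization. These scalings shifted the median of all genes by -0.19 and 0.0218. Without library 3 the count was 9357, and 8 of the 9 lists were still called.

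**Figure D2:**
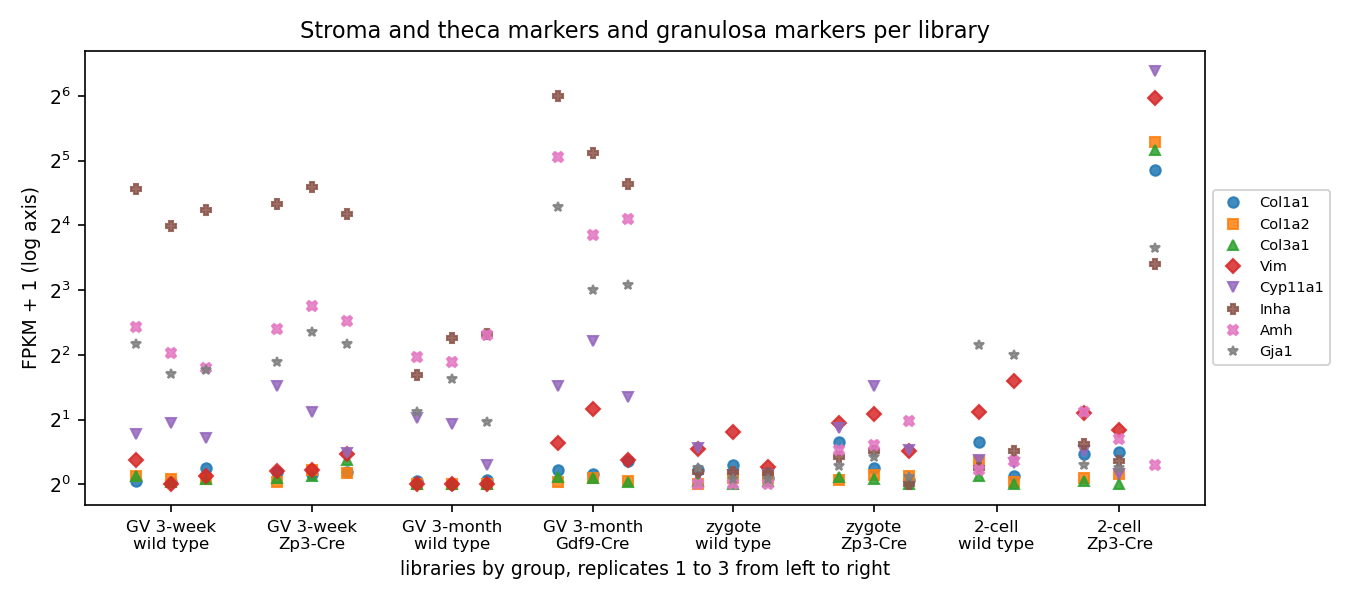
FPKM + 1, on a log axis, of the stroma and theca genes Col1a1, Col1a2, Col3a1, Vim and Cyp11a1 and the granulosa genes Inha, Amh and Gja1, with a point for each of the 23 libraries. Deletion 2-cell library 3 had 27.9 to 82.3 FPKM of the first 5 genes, and the 3-month Gdf9-Cre libraries had 24.0 to 63.3 FPKM of Inha.

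**Figure D3:**
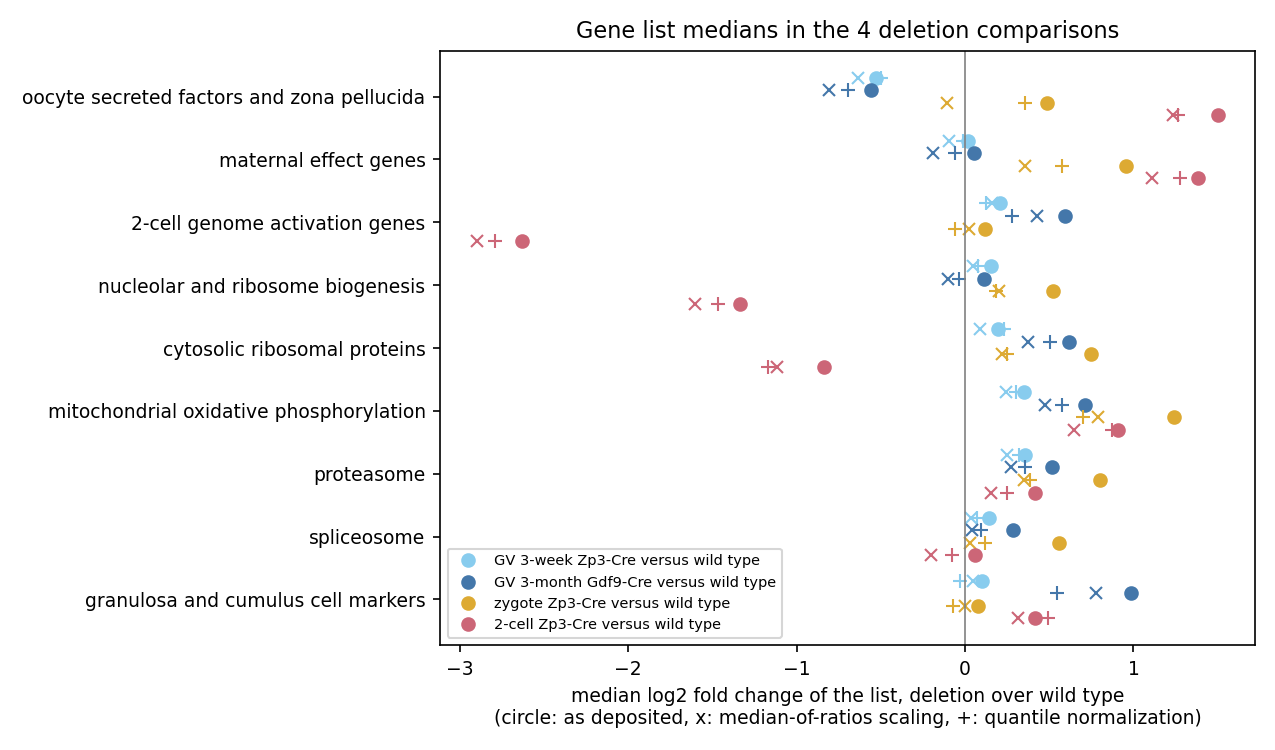
Median log2 fold change, deletion over wild type, of 9 gene lists in the 4 deletion comparisons, with circles for values as deposited, diagonal crosses for median-of-ratios scaling and upright crosses for quantile normalization. Activation genes lay at -2.63 in 2-cell embryos, and the sign depended on the scaling for maternal effect and granulosa genes in 3-week oocytes, maternal effect and nucleolar genes in 3-month oocytes, secreted, activation and granulosa genes in zygotes, and spliceosome genes in 2-cell embryos.

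The step from zygote to 2-cell embryo was smaller after maternal deletion in either direction. A set of 672 genes rose between these stages in the average of both genotypes, with a median log2 change of 4.08 in wild type and 1.11 after deletion. The test of the difference between genotypes called 632 of them (94.0%) lower and none higher. The median difference was -3.08 (quartiles -3.80 and -2.33; camera p = 0.00433 with an estimated correlation). A set of 112 genes fell between the stages, with a median change of -3.06 in wild type and -1.62 after deletion. Of these, 96 (85.7%) were called higher and 7 lower, with a median difference of 1.46 (camera p = 2.91e-04 with an estimated correlation).

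The genes whose change was reduced most were Alppl2 (-6.44 ± 0.246 on the log2 scale, SE, adjusted p = 3.10e-13), Slc34a2 (-6.26), Crxos (-5.80) and Hspa1a (-5.66). The activation gene Dppa4 had a difference of -4.57. Rgs2 (4.23), Obox2 (3.83), Nlrp4a (3.56) and Zar1 (2.57) declined less than in wild type. Across 54 genome activation genes the median difference was -2.99, with 1 higher and 49 lower (1 and 49 over the list alone). The activation list had camera adjusted p = 7.22e-14, and 0.0428 with an estimated correlation. Across 52 nucleolar genes the median difference was -2.17, with 1 higher and 43 lower (1 and 45 over the list alone). The nucleolar list had camera adjusted p = 7.18e-13, and 3.51e-04 with an estimated correlation. Of 83 ribosomal protein genes, 2 were higher and 61 lower (2 and 66 over the list alone), and the median difference was -1.80. In camera the ribosomal list had adjusted p = 2.73e-06, and 0.662 with an estimated correlation. Of 30 maternal effect genes, 14 were higher and 5 lower (14 and 5 over the list alone), and the median difference was 0.41. In camera the maternal effect list had adjusted p = 0.00505, and 0.270 with an estimated correlation. Secreted factors and zona genes had 8 higher and 2 lower members of 16 (8 and 2 over the list alone), with a median difference of 0.55. Camera gave adjusted p = 0.0241, and 0.467 with an estimated correlation. Of 21 oocyte ubiquitin ligase genes, 12 were higher and 6 lower (12 and 6 over the list alone), and the median difference was 0.58. In camera the ligase list had adjusted p = 0.0117, and 0.308 with an estimated correlation. Under median-of-ratios scaling the maternal effect, secreted and ligase medians were 0.74, 0.88 and 0.91. This test called 7420 genes, 2955 higher and 4465 lower. The higher share of 39.8% became 50.5% under median-of-ratios scaling and 58.0% under quantile normalization, with shifts of the median of all genes by 0.17 and 0.33.

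**Figure D4:**
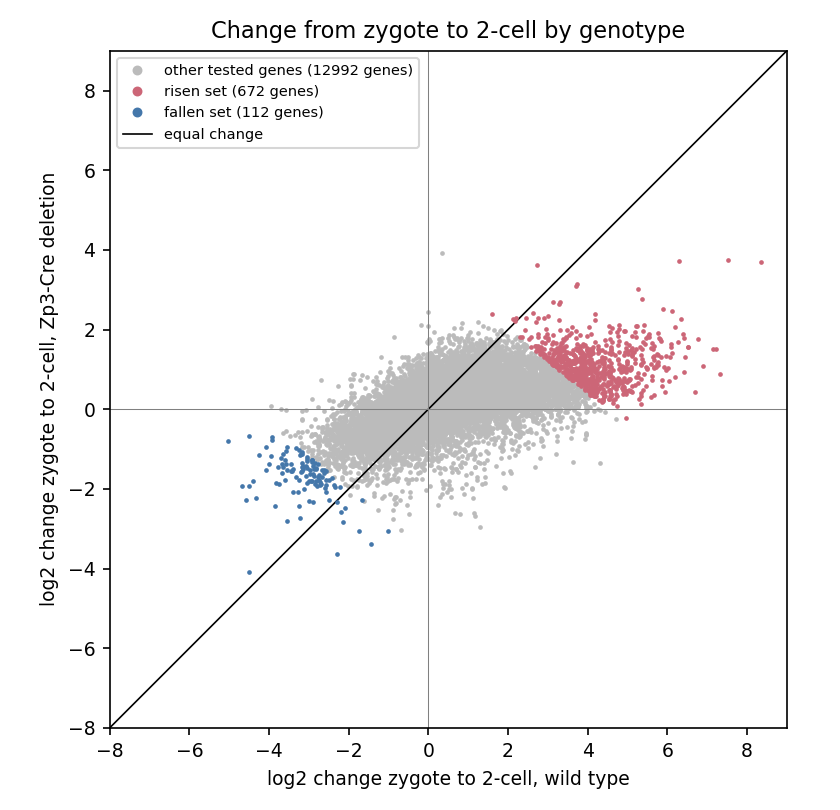
Change from zygote to 2-cell embryo on the log2(FPKM + 1) scale in wild type (x axis) and after maternal deletion (y axis), with a point per gene, the 672 genes of the risen set in red, the 112 of the fallen set in blue, other tested genes in grey and a line of equal change. Most red points lie under the line, with medians of 4.08 in wild type and 1.11 after deletion, and most blue points above it, with medians of -3.06 and -1.62.

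The wild-type GV groups differed by female age in 544 genes, fewer than in any deletion comparison. Pnpla3 fell from 66.0 ± 1.51 to 0.155 ± 0.0442 FPKM between 3 weeks and 3 months (log2 fold change -5.86 ± 0.329, SE, adjusted p = 1.25e-09). Rsph1 fell from 9.85 ± 1.14 to 0.584 ± 0.570 FPKM and the granulosa gene Inha from 18.4 ± 3.85 to 3.34 ± 0.968. The lipid-droplet coat gene Plin2 rose from 4.34 ± 0.688 to 24.2 ± 0.682 FPKM, Tceal8 from 2.2 ± 0.209 to 12.2 ± 2.54 and Zfp109 from 3.49 ± 0.593 to 15.7 ± 1.07. The deadenylase gene Cnot6l rose from 39.1 ± 0.774 to 59.8 ± 2.00 FPKM and Cnot7 from 74.8 ± 4.60 to 106 ± 7.16. Inha lost the call in 5 of 14 alternatives (adjusted p up to 0.104), and Plin2, Tceal8 and Cnot7 in 2 each. Maternal mRNA decay genes had 4 risen and 0 fallen members of 27 (5 and 0 over the list alone), with a median of 0.10. Camera gave adjusted p = 5.61e-04, and 0.00707 with an estimated correlation. Across 82 oxidative phosphorylation genes the median was -0.26, with 0 risen and 3 fallen (0 and 3 over the list alone). The respiratory list had camera adjusted p = 8.27e-09, and 0.0437 with an estimated correlation. Across 83 ribosomal protein genes the median was -0.31, with 0 risen and 1 fallen (0 and 0 over the list alone). The ribosomal list had camera adjusted p = 2.24e-06, and 0.906 with an estimated correlation. Nucleolar genes had 0 risen and 3 fallen members of 52 (1 and 4 over the list alone), with a median of -0.11. Camera gave adjusted p = 0.0440, and 0.209 with an estimated correlation. Proteasome genes had 0 risen and 2 fallen members of 44 (0 and 2 over the list alone), with a median of -0.15. Camera gave adjusted p = 0.0203, and 0.452 with an estimated correlation. Sperm markers had 0 risen and 3 fallen members of 12 (0 and 4 over the list alone), with a median of -0.45. Camera gave adjusted p = 6.46e-05, and 0.00707 with an estimated correlation. Of the 544 genes, 310 were higher and 234 lower. The count was 264 to 317 when any 1 of the 6 libraries was left out, 2482 in a fit on only these groups and 3246 with array weights.

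Wild-type zygotes differed from wild-type GV oocytes of both ages in most genes. On the log2 scale Zp3 (-5.49), Zp2 (-5.25), Khdc3 (-5.10), Npm2 (-4.75), Mos (-4.85) and Dnmt1 (-4.43) fell. Gtf2a1 (4.55), Foxn2 (4.10), Kmt2d (3.15) and Tet3 (3.18) rose. Ribosomal protein genes had 2 risen and 78 fallen members of 83 (2 and 78 over the list alone), with a median of -3.59. Camera gave adjusted p = 1.15e-07, and 0.504 with an estimated correlation. Oxidative phosphorylation genes had 6 risen and 74 fallen members of 82 (6 and 74 over the list alone), with a median of -2.84. Camera gave adjusted p = 1.15e-07, and 0.118 with an estimated correlation. Of 52 nucleolar genes, 3 were risen and 46 fallen (3 and 46 over the list alone), and the median was -1.83. In camera the nucleolar list had adjusted p = 8.19e-06, and 0.0236 with an estimated correlation. Of 44 proteasome genes, 2 were risen and 36 fallen (2 and 36 over the list alone), and the median was -2.27. In camera the proteasome list had adjusted p = 1.16e-04, and 0.135 with an estimated correlation. Of 16 secreted factors and zona genes, 3 were risen and 13 fallen (3 and 13 over the list alone), and the median was -2.65. In camera the secreted and zona list had adjusted p = 0.0393, and 0.421 with an estimated correlation. Small RNA pathway genes had 2 risen and 22 fallen members of 27 (2 and 22 over the list alone), with a median of -1.38. Camera gave adjusted p = 0.00594, and 0.200 with an estimated correlation. Of 17 H3K4 methyltransferase genes, 10 were risen and 5 fallen (10 and 5 over the list alone), and the median was 0.80. In camera the methyltransferase list had adjusted p = 0.00594, and 0.188 with an estimated correlation. Of 7 H3K4 demethylase genes, 5 were risen and 1 fallen (5 and 1 over the list alone), and the median was 0.47. In camera the demethylase list had adjusted p = 0.0210, and 0.135 with an estimated correlation. Under median-of-ratios scaling the nucleolar, proteasome and small RNA medians were -1.18, -1.44 and -0.69, and the methyltransferase and demethylase medians 1.67 and 1.31. In all 10093 genes were called, 2870 higher and 7223 lower. The higher share of 28.4% became 48.0% and 53.9% under median-of-ratios scaling and quantile normalization, which shifted the median of all genes by 0.41 and 0.54.

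From zygote to 2-cell embryo the wild type gained activation transcripts and lost maternal ones. Alppl2 rose from 0.823 ± 0.310 to 289 ± 23.3 FPKM, the activation gene Dppa4 from 0.475 ± 0.0812 to 112 ± 16 and Obox3 from 0.584 ± 0.500 to 127 ± 6.99. Kdm5b rose from 0.711 ± 0.216 to 69.2 ± 6.58 FPKM, Ccne1 from 3.85 ± 1.19 to 157 ± 13.2 and Mta2 from 1.76 ± 0.151 to 147 ± 8.0. Nop2 rose from 0.269 ± 0.166 to 71.4 ± 2.54 FPKM and Snrpc from 3.56 ± 1.15 to 174 ± 24.4. Tet3 fell from 584 ± 35.0 to 23.6 ± 2.52 FPKM and the spindle checkpoint gene Bub1b from 305 ± 22.6 to 12.4 ± 1.45. Zar1 fell from 718 ± 68.6 to 30.9 ± 0.588 FPKM, Gdf9 from 976 ± 73.0 to 111 ± 1.43 and H1foo from 1424 ± 191 to 70.6 ± 15.8. Genome activation genes had 50 risen and 1 fallen members of 54 (50 and 1 over the list alone), with a median of 4.28. Camera gave adjusted p = 2.04e-12, and 0.0635 with an estimated correlation. Across 52 nucleolar genes the median was 2.45, with 46 risen and 4 fallen (46 and 4 over the list alone). The nucleolar list had camera adjusted p = 2.16e-08, and 0.00400 with an estimated correlation. Of 83 ribosomal protein genes, 80 were risen and 2 fallen (80 and 2 over the list alone), and the median was 3.30. In camera the ribosomal list had adjusted p = 9.27e-10, and 0.409 with an estimated correlation. Of 82 oxidative phosphorylation genes, 61 were risen and 2 fallen (61 and 2 over the list alone), and the median was 1.25. In camera the respiratory list had adjusted p = 0.00162, and 0.244 with an estimated correlation. Across 16 secreted factors and zona genes the median was -0.99, with 1 risen and 11 fallen (1 and 11 over the list alone). The secreted and zona list had camera adjusted p = 9.44e-04, and 0.207 with an estimated correlation. Across 30 maternal effect genes the median was -0.59, with 8 risen and 17 fallen (8 and 17 over the list alone). The maternal effect list had camera adjusted p = 0.00401, and 0.207 with an estimated correlation. Across 21 oocyte ubiquitin ligase genes the median was -0.96, with 6 risen and 13 fallen (6 and 13 over the list alone). The ligase list had camera adjusted p = 0.00417, and 0.207 with an estimated correlation. Across 17 H3K4 methyltransferase genes the median was -0.32, with 4 risen and 11 fallen (4 and 11 over the list alone). The methyltransferase list had camera adjusted p = 0.0127, and 0.244 with an estimated correlation. The methyltransferase, maternal effect and respiratory medians were -0.76, -1.03 and 0.83 under median-of-ratios scaling. Calls numbered 9441, with 6134 higher and 3307 lower. The higher share of 65.0% became 54.2% and 43.4% under the same scalings, which shifted the median of all genes by -0.22 and -0.53.

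The Zp3-Cre effect differed between GV oocytes and zygotes for many oocyte transcripts. The effect was higher in zygotes for Zp2 (3.73 ± 0.195 on the log2 scale, SE, adjusted p = 3.11e-11), Cd9 (4.39), Mos (3.85), Khdc3 (3.21), Npm2 (2.89), Lsm4 (4.02) and Gtf2h1 (3.82). It was lower for Plin2 (-2.0), Lmo4 (-1.77), the survival gene Bcl2l1 (-1.57) and the chaperone Dnajb1 (-1.37). Plin2 lost the call in 10 of 20 alternatives (adjusted p up to 0.114), array weights and the fit on only these groups among them, and Lmo4 lost it with a pseudocount of 0.1 (adjusted p = 0.135). Across 82 oxidative phosphorylation genes the median difference was 1.02, with 43 higher and 4 lower (48 and 4 over the list alone). The respiratory list had camera adjusted p = 1.44e-07, and 0.116 with an estimated correlation. Secreted factors and zona genes had 10 higher and 0 lower members of 16 (10 and 0 over the list alone), with a median difference of 1.10. Camera gave adjusted p = 1.09e-04, and 0.154 with an estimated correlation. Maternal effect genes had 16 higher and 1 lower members of 30 (17 and 2 over the list alone), with a median difference of 0.94. Camera gave adjusted p = 1.35e-04, and 0.116 with an estimated correlation. Across 83 ribosomal protein genes the median difference was 0.69, with 31 higher and 0 lower (32 and 0 over the list alone). The ribosomal list had camera adjusted p = 0.00386, and 0.853 with an estimated correlation. Nucleolar genes had 24 higher and 1 lower members of 52 (24 and 1 over the list alone), with a median difference of 0.47. Camera gave adjusted p = 0.00432, and 0.116 with an estimated correlation. Across 44 proteasome genes the median difference was 0.44, with 18 higher and 2 lower (19 and 2 over the list alone). The proteasome list had camera adjusted p = 0.00632, and 0.387 with an estimated correlation. Of 27 small RNA pathway genes, 11 were higher and 0 lower (15 and 1 over the list alone), and the median difference was 0.43. In camera the list had adjusted p = 0.0432, and 0.467 with an estimated correlation. Of 54 genome activation genes, 3 were higher and 6 lower (3 and 4 over the list alone), and the median difference was -0.0511. In camera the list had adjusted p = 0.0339, and 0.585 with an estimated correlation. Of 62 spliceosome genes, 25 were higher and 1 lower (27 and 1 over the list alone), and the median difference was 0.40. In camera the list had adjusted p = 0.0424, and 0.403 with an estimated correlation. Under median-of-ratios scaling the spliceosome calls were 15 higher and 16 lower, and the ribosomal, nucleolar and proteasome medians were 0.28, 0.14 and 0.17. Maternal effect genes then had 13 higher and 8 lower members (median 0.47), secreted and zona genes 8 and 2 (0.61), and small RNA genes 5 and 3 (0.20). Under quantile normalization small RNA genes had 7 and 1 (0.14). Of 4050 genes called, 3084 were higher and 966 lower. That higher share of 76.1% became 39.5% under median-of-ratios scaling and 49.1% under quantile normalization, with shifts of the median of all genes by -0.23 and -0.21.

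A core of genes changed in the same direction in all 4 deletion comparisons, which share no libraries. As deposited, 856 genes were called higher and 211 lower in each. Neither count was repeated under the scalings or set against a chance number, and the scalings changed the pairwise counts. Stambpl1 had log2 fold changes of 4.56, 5.23, 3.28 and 3.63 in 3-week oocytes, 3-month oocytes, zygotes and 2-cell embryos. In the same order the fatty-acid-binding protein gene Fabp7 had 2.33, 3.02, 3.79 and 3.61, and Hoxd13 had 2.90, 3.26, 2.82 and 3.19. Pabpn1l had -4.06, -4.13, -2.34 and -0.63, Insm1 had -2.97, -3.10, -2.85 and -0.91, and Rbm4 had -2.47, -1.88, -1.58 and -2.68. Averaged over the comparisons, Ash2l was higher by 1.20 ± 0.0452 (SE, adjusted p = 4.48e-14). The repair factor Trp53bp1 (-1.43) and the imprinted genes Igf2r (-1.16) and Gnas (1.25) also had an average effect. Oxidative phosphorylation genes had 65 higher and 2 lower members of 82 (66 and 3 over the list alone), with a median effect of 0.87. Camera gave adjusted p = 3.17e-08, and 0.165 with an estimated correlation. Proteasome genes had 35 higher and 1 lower members of 44 (35 and 1 over the list alone), with a median effect of 0.42. Camera gave adjusted p = 3.23e-05, and 0.229 with an estimated correlation. Across 54 genome activation genes the median effect was -0.25, with 8 higher and 31 lower (8 and 32 over the list alone). The activation list had camera adjusted p = 3.23e-05, and 0.262 with an estimated correlation. The proteasome median was 0.14 and the activation median -0.47 under median-of-ratios scaling. The activation average was carried by 2-cell embryos, with 2 risen and 48 fallen activation genes and a median of -2.63. The activation list had more rises than falls in 3-week oocytes (14 and 3, median 0.21), 3-month oocytes (30 and 3, median 0.59) and, as deposited, in zygotes (13 and 1, median 0.12). The average effect called 9147 genes, 6008 higher and 3139 lower. A higher share of 65.7% became 41.3% under median-of-ratios scaling and 48.4% under quantile normalization, with shifts of the median of all genes by -0.22 and -0.16.

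As deposited, pairs of comparisons shared more higher genes than independent lists would. The numbers were 1608 against 890.4 for 3-week oocytes and zygotes, 2373 against 1664 for 3-month oocytes and zygotes, and 2818 against 1803 for zygotes and 2-cell embryos. For 2-cell embryos they were 1349 against 937 with 3-week oocytes and 1908 against 1751 with 3-month oocytes. Shared lower genes numbered 668 against 178, 810 against 239 and 519 against 462 for the first 3 of these pairs. They numbered 443 against 457 and 522 against 617 for GV oocytes and 2-cell embryos. The correlation of log2 fold changes across genes was 0.385 and 0.352 between GV oocytes and zygotes, 0.271 between zygotes and 2-cell embryos, and 0.0672 and -0.0266 between GV oocytes and 2-cell embryos.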

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

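The results below differed between groups by a test of the difference between deletion effects itself. The tests of why the zygote-to-2-cell change was smaller, the test of stroma and theca markers and the test of where granulosa markers peaked were chosen only after the results were seen. The splits of the samples, the position of deletion 2-cell library 3 between the groups and the scaling of granulosa markers were fixed before their results were seen.

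The Zp3-Cre effect differed between zygotes and GV oocytes in 4050 genes and 9 gene lists. The genes with the largest higher effect in zygotes were Eif3j1 (7.15), Mir7035 (6.89), Srp54c (4.60), Pnpla3 (4.52) and Cd9 (4.39), on the log2 scale. Those with the largest lower effect were Eif3j2 (-7.14), Plin2 (-2.0), Alyref2 (-1.98), Tceal8 (-1.95) and Lmo4 (-1.77). Of the 20 alternatives 10 took the call from Plin2, 4 from Tceal8 and 1 each from Lmo4 and Eif3j1, and 3 of 18 took it from Mir7035 (adjusted p up to 0.108). Eif3j1 and Eif3j2 are near-identical copies that moved by almost the same amount in opposite directions, so reads can have been assigned to either copy, and neither value is read as a change of the gene. Among 100 splits of these samples, 7 called at least as many genes, the real one included, with a highest other count of 4638, so chance cannot be excluded by this count. All 7 keep the true genotypes in at least 1 of the stages. The 79 splits that keep them in neither called at most 2 genes. Such splits mix genotypes within groups, which puts any difference between the labelled groups into the spread, so low counts were bound to follow. The splits therefore do not tell the deletion from anything else that went with the labels.

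Between 2-cell embryos and zygotes the effect of maternal deletion differed in 7420 genes and 6 gene lists. Rgs2 (4.23), Obox2 (3.83), Nlrp4a (3.56), Oas1h (3.41) and Dnajb4 (3.23) had the largest higher effect in 2-cell embryos, and Alppl2 (-6.44), Slc34a2 (-6.26), Crxos (-5.80) and Hspa1a (-5.66) the largest lower effect. The set of genes that rise between the stages had a median difference of -3.08 and the set that falls one of 1.46. With 2 wild-type 2-cell libraries no splits were counted for this test.

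The effect in 3-month Gdf9-Cre oocytes differed from that in 3-week Zp3-Cre oocytes in 673 genes and 3 gene lists. Pnpla3 (5.69), Inha (3.06), Cox8c (2.65), Sepp1 (2.10) and Elf3 (2.02) had the largest higher effect with Gdf9-Cre, and Tceal8 (-2.86), Zfp109 (-2.68), Rbm44 (-1.64) and Mt1 (-1.47) the largest lower effect. With a pseudocount of 0.1 Inha, Sepp1 and Mt1 lost the call (adjusted p = 0.124, 0.0780 and 0.216). Of 100 splits, 12 called at least as many genes, the real one included, and the highest other count was 4981, several times the real one. All 12 keep the true genotypes in at least 1 of the models, and the 79 splits that keep them in neither called at most 1 gene. Low counts in those splits were bound to follow, as above, so they do not tell the deletion from anything else that went with the labels. The count of 673 cannot exclude chance for the difference between models. Pnpla3, Inha, Tceal8 and Zfp109 also differed between the wild-type age groups, by -5.86, -2.17, 2.03 and 1.90. Inha lost that call in 5 of 14 alternatives. Female age and collection stay open as sources of their difference, untested. Cre driver stays open too, except for Pnpla3, whose difference lay between groups labelled wild type.

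For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split alone reached its count in each, 1 of 10. It called 4081 genes in 3-week oocytes against at most 1 in another split, 6818 in 3-month oocytes against 0, 6431 in zygotes against 1, and 544 between the wild-type ages against 0. For wild-type zygotes against GV oocytes the real split, with 10093 genes, was the only 1 of 84 to reach its count. The highest other called 8099. Chance labelling is thus unlikely only for this last comparison. It cannot be judged from 10 splits. Splits that mix the groups put their difference into the spread, so low counts were bound to follow. Chance between animals or collections was not tested.

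The smaller zygote-to-2-cell change was weighed against technical causes. Scaling between libraries was excluded as its whole cause, since 95.2% of the risen set, defined anew under each, was called lower under median-of-ratios scaling and 94.3% under quantile normalization. RNA of other cells in deletion 2-cell library 3 was excluded as well, since without that library 98.3% of the set, 699 of 711 genes, was called lower. Earlier collection or slower development of the deletion embryos stays open. The fallen set changed by 53% of the wild-type amount, a smaller change in both sets, which an earlier point in development could also give, and the hours after fertilization are not given. A loss of genome activation through missing maternal CFP1 cannot be told apart from such a delay here.

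Transcripts of other cells in deletion 2-cell library 3 may come from ovarian stroma or theca cells, a hypothesis from marker lists fixed in advance. Of the 9 stroma and theca markers detected in 2-cell libraries, 77.8% were at least 4 times as high as in either other deletion library, just under the 80 set for a clear result, and 65.0% of granulosa and 66.7% of blood markers were too. Of the 13 stroma and theca markers in the table, 1 has a mean FPKM of at least 1 in wild-type 2-cell embryos, and no other list holds any of them. Cyp11a1, Vim and Col1a2 were at 82.3, 61.9 and 38.2 FPKM, against at most 0.301, 2.01 and 0.288 in wild-type 2-cell libraries. This argues against wild-type embryos as the source of these markers. Whether the library also held wild-type embryos, or embryos further in activation, stays open. The 48 activation genes lay at a median of 14.1% of the way to wild type (quartiles 3.49 and 30.6). That is between the limits of 10 and 25 set beforehand. Which cells were lysed is not given.

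Granulosa markers in 3-month Gdf9-Cre oocytes may come from attached granulosa cells. Of the 13 called markers 11 (84.6%) had their highest value in library 1, against 41.7% of all genes called higher, as RNA carried over in varying amounts would give. Abundant markers were Inha, at most 63.3 FPKM, and Amh, at most 32.4, while Fshr stayed at 0.634, 0.252 and 0.447. Wild-type 3-month oocytes hold 9 of the 25 markers at a mean FPKM of at least 1, so the list is not free of oocyte transcripts. Scaling between libraries stays open as a part of the cause, since 10 and 7 members were called higher under the scalings, the lower number at the edge of the limits set beforehand. An effect of the deletion on the oocyte's own transcripts was not tested.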

How the results depend on the processing

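Alternatives were fixed in advance except the gene lists and named genes of 2-cell embryos without deletion library 3, the stage sets in zygotes and the gene lists under each scaling, which were chosen only after results were seen. Of 229 values under the alternatives fixed in advance that leave out no library, 184 kept direction and side of the threshold, or stayed within 1.5 times the count. Of 146 values that leave out a library, 131 did. Of 17412 values of named genes, 16747 kept both, 618 lost the call, 45 gained it and 2 changed sign. Where the cause of a change is not given, the cause was not tested.

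The wild-type age count of 544 was 3246 with array weights and 2482 in a fit on only the groups compared. The count of 673 for the difference between GV models was 3228 and 2448 under these, and 363 with a pseudocount of 0.1. A log2 fold change of at least 1 in size left 683 genes in 3-week oocytes, 1861 in 3-month oocytes, 2281 in zygotes and 5122 in 2-cell embryos, by construction fewer.

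With an estimated inter-gene correlation the lists called became 0 for 3-week oocytes, 3-month oocytes, zygotes, the difference between zygotes and GV oocytes, that between GV models and the average. They became 2 for 2-cell embryos and for the difference between 2-cell embryos and zygotes, 3 for wild-type age, and 1 for each wild-type stage step. With median-of-ratios scaling 8 lists were called in 3-month oocytes, 4 in zygotes, 5 for the difference between zygotes and GV oocytes and 5 for the average.

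Shared genes were counted under median-of-ratios scaling and quantile normalization. For the GV models 1182 and 1332 higher genes were shared. For 3-week oocytes and zygotes these were 713 and 849 higher and 1191 and 1142 lower, and for 3-month oocytes and zygotes 1008 and 1097 higher and 1841 and 1727 lower. For 3-week oocytes and 2-cell embryos median-of-ratios scaling gave 733 higher and 673 lower. For 3-month oocytes and 2-cell embryos there were 965 and 1224 higher and 989 and 843 lower, and for zygotes and 2-cell embryos 1503 and 1751 higher and 1435 and 1121 lower. Under median-of-ratios scaling Nr5a2 in zygotes was at -0.00166 and the difference for Esr2 between zygotes and GV oocytes at -0.0104, each positive as deposited. Of the zygote stage sets, defined anew under each alternative, the risen set, called lower for 32.8% as deposited, was called lower for 18.3% with a pseudocount of 0.1 and 80.9% with median-of-ratios scaling, and the fallen set, called higher for 42.5% as deposited, for 28.2% and 25.8% under the scalings.

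Leaving out 1 library gave 264 to 317 genes for wild-type age, where each of the 6 libraries moved the count. For the difference between GV models it gave 360 to 766, lowest without wild-type 3-week library 1 and highest without Zp3-Cre library 3. Without a wild-type 2-cell library that group holds 1 sample, which is assumed to vary like the other groups. The replicate numbers as a block called 3 lists in 3-week oocytes. Profiles of the same number correlated between -0.0689 and 0.0576 across groups, so the numbers do not pair samples.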

Other observations

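The test of maternal transcripts below was chosen only after the zygote result was seen, and its condition on the 95% upper bound was added after the ratio was seen, which left open what the ratio alone would have excluded. Single oocyte genes point to a hypothesis. Zp2, Zp3, Mos and Khdc3 fall from GV oocyte to zygote in wild type, by -5.25, -5.49, -4.85 and -5.10 on the log2 scale, and were higher in deletion zygotes. Less loss of maternal transcripts after deletion may give such values. Of 1804 genes that fall between the stages, 766 (42.5%) had a higher deletion effect in zygotes, against 33.0% of other genes of the same expression level, a ratio of 1.29. With the genes defined anew under each scaling, 1082 and 850 of them, the ratio was 1.35 under median-of-ratios scaling but 0.978 under quantile normalization, with an upper bound of 1.09, so the question stays open. Obox1, Obox5 and Tet3 were lower in the same zygotes.

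Pnpla3 marked the 3-week wild-type oocytes, at 64.3, 66.5 and 67.1 FPKM, and was at most 4.81 FPKM in every library of the other groups, Zp3-Cre oocytes of the same age included. Mt1 was at 5.35 ± 0.391 FPKM in 3-week wild-type oocytes and 78.3 ± 4.96 after Zp3-Cre deletion, while the 3-month wild-type libraries held 0.556, 1.58 and 1.49 FPKM and the Gdf9-Cre libraries 6.84, 12.8 and 7.48. The difference between the Mt1 effects, -1.47 on the log2 scale, was -0.98 with a pseudocount of 0.1 and no longer called (adjusted p = 0.216). Age and collection cannot be separated for the Pnpla3 level in wild type, nor these and Cre driver for the Mt1 level of 78.3 FPKM, and none was tested as a cause.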
